A study of Mus musculus with 7 samples.

How the data were processed

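The series profiled wild-type CD1 mouse spermatocytes at postnatal days 12 and 17 by chromatin immunoprecipitation and sequencing. Of its 7 samples, 5 had files used here: H3K27me3 and H3K4me3 at P12, the same marks at P17 as pools of 2 replicates per the labels, and EED at P17. The input libraries of both stages were not analysed here. Groups were taken from the sample titles, since the antibody field of the P17 H3K4me3 sample names H3K27me3.

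Reads were aligned with Bowtie to mm9 and handled with SAMtools and HTSeq, per the submitters' processing notes, which assign no role or version to the tools. The deposited gene-body files hold raw read counts per gene symbol for H3K27me3 at each stage, made by the authors with multiBamCov per the file naming, with no normalization and no recorded input subtraction. The deposited peak files hold peak coordinates called by the authors with MACS, per the peak names in the files, at the level 5 named for a false discovery rate in the file names. These lists carry no score, height or p-value. Caller version and settings and aligner parameters are not given in the sources used here. Peak names are numbered, and 13.1% of the numbers were missing from the P12 H3K27me3 list, 11.0% from the EED list, 0.255% from the P17 H3K4me3 list and 0 from the others. The P17 histone-mark lists were called on pooled replicates and the EED list on 1 replicate, per the labels.

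The count files held 23530 entries each, with 13462873 reads at P12 and 26664736 at P17; 501 and 363 entries were at 0. The 13 entries with the most reads at P12, all multicopy or repeat-derived features, took 14.9% of reads at P12 and 14.3% at P17. Rn45s, with 43756 and 207433 reads, was not among them and stayed in the alternative totals without multicopy entries. The 146 symbols with several entries (310 entries, 10.6% and 10.1% of reads) stayed in the totals and were left out of per-gene work. Of 23366 symbols, 21525 were found in a GRCm38 gene table and 1709 as synonyms in it. That table was used for names only, and none of its coordinates were used.

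Counts were scaled to the total reads counted in the file (CPM). The log2 ratio P17/P12 was computed with a pseudocount of 1 read scaled to each library, for genes with at least 20 reads over both libraries. Each ratio has an exact conditional (Clopper-Pearson) 95% interval. A gene was counted as higher or lower when it was over 2-fold different and its interval excluded a ratio of 1, and called above or below the typical gene when its interval lay wholly above or below the all-gene median. With 1 library per stage these counts compare the libraries, not the stages, and have no replicate check.

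Before the data were examined, 14 gene lists were fixed: Hox genes, somatic developmental transcription factors, developmental signalling genes, Sertoli cell markers, Leydig and other testis somatic markers, spermatogonial, meiotic prophase, spermiogenesis, Polycomb and trithorax, cell cycle inhibitor, housekeeping, imprinted, olfactory and vomeronasal receptor, and X-linked genes. Each list's median log2 ratio was placed among medians of 10000 random lists of the same size matched on mean CPM in 20 bins, and its median level among unmatched random lists. The percentile describes these 2 libraries only. A further 2 lists, immediate-early response genes and replication-dependent histone genes, were written after the highest ratios had been seen.

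Genes named in the text followed a rule fixed beforehand. It took, of genes with at least 50 reads and an interval excluding 1, the 10 highest and 10 lowest log2 ratios. It added the 10 highest P17 levels, the highest 2 levels and the highest and lowest ratio of each list, and Eed, Ezh2, Suz12 and Ezh1. Near-identical families were named as families. A result that the rule would have named is not reported here. The rule's highest-scoring peaks per set could not be taken without scores, so peaks were drawn from the 5 widest of each set and from the domains with the most EED peaks, chosen after the lists had been seen.

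Peak sets were compared by the share of peaks overlapping another set by at least 1 bp, with Wilson 95% intervals. Positions were tested against 1000 rotations of each chromosome's peaks within the span of all peaks (one-sided, Benjamini-Hochberg over 15 pairs). Coordinates are mm9 and counted from 1. Widths of H3K27me3 peaks with and without EED were compared by a permutation test of 100000 resamples and by rotating the H3K27me3 peaks against EED. This took the place of the comparison of peak scores that had been fixed. EED at H3K27me3 peaks with and without a P12 counterpart was compared by Fisher's exact test and by Mantel-Haenszel odds ratios over 10 and 50 width classes and without the widest of the 10, and the X chromosome was compared with autosomes by Fisher's exact test; all of these were added after the files had been seen.

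Alternatives were edgeR TMM factors, median-of-ratios factors, minimum reads of 1 or 100, a pseudocount of 5, totals without multicopy entries, overlap of 50% of the peak, peaks within 1 kb merged or counted, and the wider part of each set split at its median width. Sorting promoters by mark, genes near EED peaks, levels per kb of gene and GC content were not analysed, since no mm9 annotation or genome was used here. The code was tested on simulated data for the P17 against P12 comparison over 21764 genes. Intervals covered the true ratio in 95.6% of genes, and of 21564 unchanged genes 25 were called higher and 27 lower. The simulated libraries were drawn from a shared profile with counting (Poisson) error only. These figures therefore check the code and do not give the error rate of the observed calls. Of the 200 changed genes, 99.0% were recovered at a log2 ratio of 1.5 and 100% at 2.5. Of 100 random lists, 2% fell outside the central 95%, and 3 of 40 randomly placed peak sets had p of 0.05 or less. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.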

Results

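Chromatin from wild-type CD1 mouse spermatocytes was profiled by chromatin immunoprecipitation and sequencing at postnatal days 12 (P12) and 17 (P17), an interval in which germ cells advance through meiotic prophase. H3K27me3, the repressive mark deposited by Polycomb repressive complex 2 (PRC2), and H3K4me3, a mark of promoters, were profiled at both stages. EED, a core PRC2 subunit, was profiled at P17. The series title names repression of soma-specific genes by PRC2 in male germ cells as its subject, and the comparisons below describe where the marks and EED lay at each stage. Of 7 samples, 5 had files that were analysed here, with 1 file set per mark and stage; the P17 histone-mark files each pooled 2 replicates, and input libraries were not analysed here. There are no replicates to compare, so no p-value was computed across genes, and every interval of a gene's ratio covers counting error only. Intervals of peak shares and odds ratios treat called peaks as independent and do not cover differences between replicates. The H3K27me3 gene-body counts summed to 13462873 reads at P12 and 26664736 reads at P17, with a median of 178 and 354 reads per gene entry.

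Between P12 and P17, H3K27me3 over gene bodies was higher by under 2-fold at developmental regulators. Relative to the library, it was lower at meiotic genes (median log2 ratio -0.18) but also in other lists, such as Polycomb and trithorax (-0.19) and X-linked genes (-0.32). The largest ratios lay at other genes, but a ratio is not an amount of signal. Zfp36, with the highest ratio, went from 1.93 to 11.4 CPM, and Hoxa3, with the highest Hox level, from 366 to 444 CPM. Of 21808 genes with at least 20 reads, 561 were over 2-fold higher at P17 with a counting interval excluding a ratio of 1, and 73 were over 2-fold lower. None of the Hox genes, somatic developmental transcription factors or developmental signalling genes described below was among the 561. This depends on scaling for Sox18, at a log2 ratio of 0.99 here but 1.07 with TMM or median-of-ratios factors. Immediate-early and histone genes, in lists written after the highest ratios had been seen, had 21 of 46 and 18 of 38 over 2-fold higher. The median log2 ratio of all genes was -0.08, with a 10th to 90th percentile range of -0.34 to 0.47. Among those with at least 50 reads, the highest log2 ratios belonged to Zfp36, which encodes an mRNA-decay factor induced by growth signals, at 2.54 (95% interval 1.99 to 3.20; 26 and 305 reads), and to the immediate-early gene Ier2 at 2.49 (2.17 to 2.85; 81 and 909 reads). Next came 0610038B21Rik at 2.48, the ciliary small GTPase gene Rab34 at 2.47, the Ras-family gene Rap2b at 2.46, Csnka2ip at 2.39 and the RNA-binding protein gene Zfp36l2 at 2.38. Gm15417 and the histone H2B gene Hist1h2bl both stood at 2.35 and Ppdpf at 2.34. Hist1h2bl rested on 4 and 46 reads and belongs to a family of near-identical copies, so its assignment of reads is uncertain.

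Among genes with at least 50 reads and an interval excluding a ratio of 1, the lowest log2 ratio was that of Gm10190 at -1.40, followed by Hmgn2, which encodes a nucleosome-binding protein, at -1.31 (-2.19 to -0.54; 31 and 24 reads). Cwc22, a splicing factor gene whose copy number varies among mouse strains, was the only well-covered member of this group, at -1.28 (-1.36 to -1.20; 2836 and 2307 reads). The ribosome-rescue gene Pelo and the Integrator subunit gene Ints5 both stood at -1.15, and Taf7, a TFIID subunit gene, at -1.14. The isoprenoid-synthesis gene Idi1 followed at -1.11, the gonadotropin-releasing hormone gene Gnrh1 at -1.07 and F630028O10Rik at -1.05. The beta-defensin gene Defb34 stood at -1.04. Except for Cwc22, these genes had few reads: with at least 100 reads required, 493 genes were over 2-fold higher and 3 lower.

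Genes of somatic development held a somewhat larger share of the H3K27me3 reads at P17. Without input, higher enrichment over background in the P17 pool cannot be told apart from a stage difference, here or in the other lists. The 39 Hox genes, which set position along the body axis, had a median log2 ratio of 0.41, above the central 95% range of -0.13 to 0.04 given by 10000 random lists matched on level. Intervals of 36 Hox genes lay above the ratio of the typical gene, the all-gene median, and that of 1 lay below it. Random lists took genes regardless of position, so they do not allow for neighbours, such as clustered Hox genes, changing together. Hoxc4 had the highest ratio at 0.87 (0.65 to 1.09) and Hoxa4 the lowest at -0.52 (-0.78 to -0.26). Hoxa3 and Hoxd3 had the highest Hox levels at P17, 444 and 357 CPM (read counts scaled to the library total), against 366 and 272 CPM at P12. Among 114 somatic developmental transcription factors the median was 0.32 (random range -0.09 to 0.00), with 107 intervals above and 0 below the typical gene. Sox18, a factor of vessel development, stood highest at 0.99, and T, the mesoderm factor Brachyury, lowest at -0.16. Pax5 and Pax7, factors of lymphoid and muscle progenitors, had the highest levels at P17, 433 and 371 CPM. For 39 developmental signalling genes the median was 0.19 (random range -0.12 to 0.05), with 32 above and 0 below. The Wnt antagonist gene Dkk1 led at 0.69, Wnt7a was lowest at -0.10, and Bmp6 and Wnt7b had the highest levels at P17, 194 and 181 CPM.

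**Figure D1:**
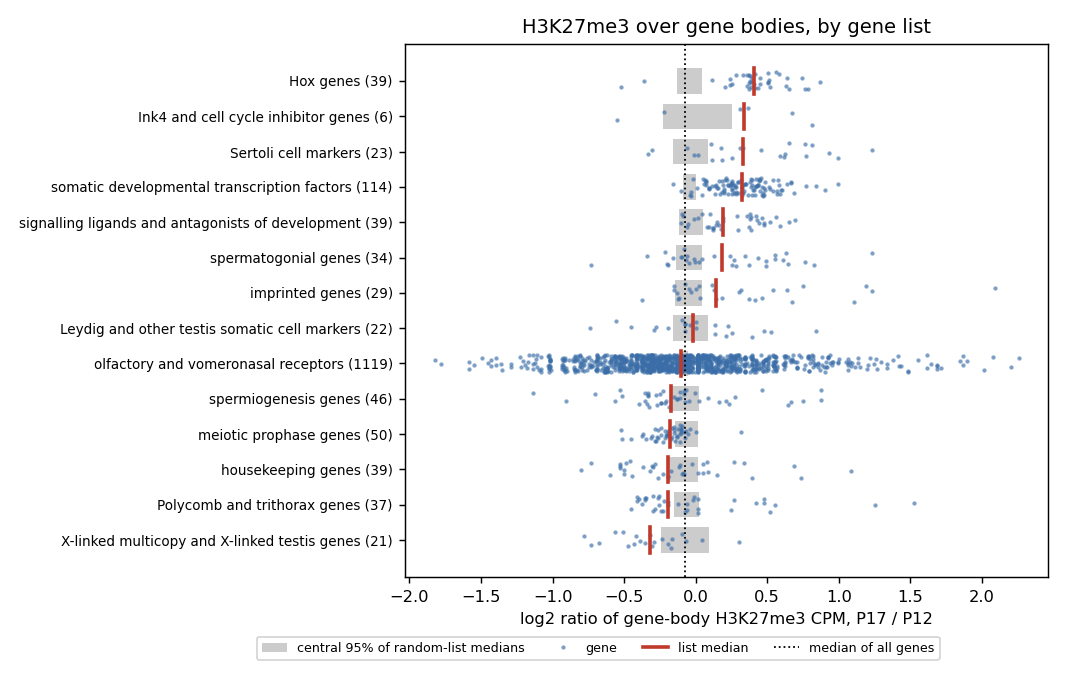
Log2 ratio of H3K27me3 gene-body CPM, P17 over P12, on the horizontal axis for 14 gene lists fixed in advance, with measured members in parentheses; points are genes, red bars list medians, grey bands the central 95% of random-list medians and the dotted line the median of all genes. The Hox median stands at 0.41 and the X-linked median at -0.32.

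Markers of testicular somatic cells formed 2 lists, which were not tested against each other. The 23 measured Sertoli cell markers had a median of 0.33 (random range -0.16 to 0.09), with 12 intervals above and 1 below the typical gene, and a median of 0.59 over the 19 markers with at least 100 reads. The intermediate filament gene Vim reached 1.23 (1.03 to 1.45), and the nephric and gonadal regulator Wt1 had the highest P17 level, 135 CPM, with a ratio of 0.77. Fshr, the follicle-stimulating hormone receptor gene, had the next level at 113 CPM and a ratio of -0.06, and Tjp1, a tight-junction gene, was lowest at -0.33. Of the Sertoli list, 3 genes also belonged to other lists. For 22 markers of Leydig and other somatic cells the median was -0.02, inside the random range of -0.16 to 0.09, and it was 0.06 with TMM scaling. In that list 7 were above and 4 below the typical gene, from the Hedgehog effector Gli1 at 0.84 to the macrophage marker Cd68 at -0.74. The Cd68 ratio rested on 24 and 28 reads, with an interval of -1.60 to 0.09. Gli1 and the growth factor receptor gene Pdgfra held the highest P17 levels of the list, 101 and 107 CPM.

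Spermatogonial genes stood higher and meiotic genes lower. The 34 spermatogonial genes had a median of 0.19 (random range -0.14 to 0.04), with 17 above and 3 below the typical gene. Utf1, a gene of undifferentiated spermatogonia, led at 1.23 (1.02 to 1.45), while Rhox13 stood at -0.73. The stem cell genes Gfra1 and Zbtb16 had the highest P17 levels, 349 and 224 CPM, yet ratios of -0.22 and -0.34. The 50 meiotic prophase genes had a median of -0.18, below the random range of -0.14 to 0.01, with 1 above and 17 below. Sycp3, which encodes an axial element of the synaptonemal complex, was lowest at -0.52 (-0.88 to -0.16), the cohesin gene Rec8 highest at 0.32, and Tex14 and Tdrd9 had the highest P17 levels, 87.9 and 87.8 CPM. For 46 spermiogenesis genes the median of -0.17 lay at the edge of the random range (-0.17 to 0.02; percentile 2.56), with 5 above and 7 below. Over the 34 of these genes with at least 100 reads it was -0.13 (percentile 13.6). Its extremes were the testis heat-shock gene Hspa1l at 0.88 and the protamine gene Prm3 at -1.14, the latter on 13 and 11 reads. Zpbp and Ropn1 had its highest P17 levels, 84.6 and 47.2 CPM.

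Of the PRC2 genes, Eed stood at -0.37 (-0.62 to -0.12), below the typical gene. The intervals of Suz12 at -0.25, Ezh2 at -0.19 and Ezh1 at -0.06 spanned the typical gene, and Ezh1 stood on the other side of 0 with TMM scaling. The whole list of 37 Polycomb and trithorax genes had a median of -0.19 (random range -0.15 to 0.03), with 9 above and 10 below. Its highest ratio belonged to the PRC1 gene Pcgf2 at 1.52 (1.32 to 1.74), over 2-fold higher, and its lowest to Pcgf6 at -0.45. Jarid2 and Mll3 had the highest P17 levels, 154 and 135 CPM. Of 6 measured cell cycle inhibitor genes (median 0.34, random range -0.23 to 0.25), Cdkn1b stood at 0.81 and Cdkn1c at 0.67. The neighbouring Cdkn2a and Cdkn2b stood at -0.22 and -0.55, and Cdkn1c and Cdkn2a had the highest levels at P17, 69.5 and 68.7 CPM.

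The remaining lists split as follows. Among 29 imprinted genes (median 0.14, random range -0.14 to 0.05), 16 were above and 2 below the typical gene, from Ndn at 2.09 to Nespas at -0.38. Kcnq1 and Gnas held the highest imprinted levels at P17, 369 and 245 CPM. The 39 housekeeping genes had a median of -0.19, at the edge of the random range (-0.19 to 0.01; percentile 2.66), from the lysosomal gene Gusb at 1.09 to the cytochrome c gene Cycs at -0.80. Over the 27 housekeeping genes with at least 100 reads it was -0.11 (percentile 38.9). Reep5 and Gpi1 had its highest P17 levels, 27.9 and 27.7 CPM. The 1119 olfactory and vomeronasal receptor genes had a median of -0.11 (random range -0.09 to -0.06), with 49 above and 45 below; Olfr242 at 2.26 rested on 2 and 24 reads and Olfr1280 at -1.82 on 16 and 8 reads. Over the 195 receptor genes with at least 100 reads the median was -0.12 (percentile 5.63). Olfr56 and Vmn2r60 led in level at 57.1 and 34.6 CPM. The 21 X-linked genes had the lowest median of the 14 lists, -0.32 (random range -0.24 to 0.09), with 0 above and 5 below. They ran from Rhox2a at 0.31 to Rhox1 at -0.78, and the zinc finger gene Zfx had a P17 level of 12.4 CPM. Rhox2a rested on 6 and 15 reads, with an interval of -1.11 to 1.99. TMM scaling raised all list medians alike, to -0.11 for meiotic prophase, -0.10 for spermiogenesis, -0.12 for Polycomb and trithorax and for housekeeping, -0.03 for receptor and 0.22 for imprinted genes.

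By level alone, developmental genes ranked high at both stages, as did several other lists. The median Hox gene carried 38.2 CPM at P12 and 54.6 CPM at P17, at percentiles 99.9 and 100 among random lists of equal size. The median somatic transcription factor carried 71.6 and 93.0 CPM (percentile 100 at both stages), while housekeeping genes carried 5.57 and 4.99 CPM (percentiles 0.05 and 0.02). Percentiles were also high for spermatogonial genes (99.7 and 99.94), imprinted genes (99.87 and 99.99), Leydig and other somatic markers (99.01 and 98.9) and meiotic prophase genes (99.63 and 97.95). Gene lengths were not used, so long genes gather more reads in these levels. The highest entries of all came from multicopy or repeat-derived sequence. Mir684-1 held 45513 CPM and Snora19 33779 CPM at P17, a family of near-identical Gm genes that includes Gm2913 and Gm3701 held about 5805 and 5736 CPM per member, and Rn45s, the ribosomal RNA precursor, held 3250 CPM at P12 and 7779 CPM at P17 (log2 1.26). Among the other entries the protocadherin entry Pcdha4-g led with 1425 CPM and a ratio of 0.46. The long neuronal genes Asic2, Cdh13, Macrod2, Camta1 and Ptprd followed, with 1392, 1303, 1242, 1217 and 1181 CPM.

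The deposited peak lists showed wider H3K27me3 domains at P17. At P12 there were 13028 H3K27me3 peaks covering 21.6 Mb with a median width of 1090 bp, and at P17 there were 26387 peaks covering 86.4 Mb with a median width of 2529 bp. H3K4me3 peaks numbered 44142 over 74.6 Mb at P12 and 51603 over 106 Mb at P17, with median widths of 1483 and 1716 bp. EED peaks at P17 were few and narrow, 2701 over 1.48 Mb with a median of 303 bp, and merging those within 1 kb left 1334. The widest P17 H3K27me3 peaks (mm9) lay on chromosome 15 at 102738509 to 102834200 (95692 bp), chromosome 11 at 96129003 to 96219277 (90275 bp) and chromosome 2 at 74482891 to 74555463 (72573 bp). The next widest were chromosome 11 at 96025689 to 96071294 and chromosome 4 at 139355374 to 139400747. The widest P12 H3K27me3 peak, on chromosome 6 at 52149265 to 52192271 (43007 bp), had no P17 H3K27me3 peak over it, whereas 25 EED peaks lay within it. It lay inside a 133 kb stretch without any P17 H3K27me3 peak, which held 26 P12 H3K27me3 peaks and 47 EED peaks. The cause of this gap in the list was not tested, so it is not read as loss of the mark. The X chromosome held 0.921% of P12 H3K27me3 peaks (Wilson 95% interval 0.771% to 1.10%) and 0.443% at P17 (0.370% to 0.531%), against 2.72% and 2.74% of H3K4me3 peaks. Numbers and widths of called peaks move with depth and pooling, so their totals were not tested between stages.

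**Figure D2:**
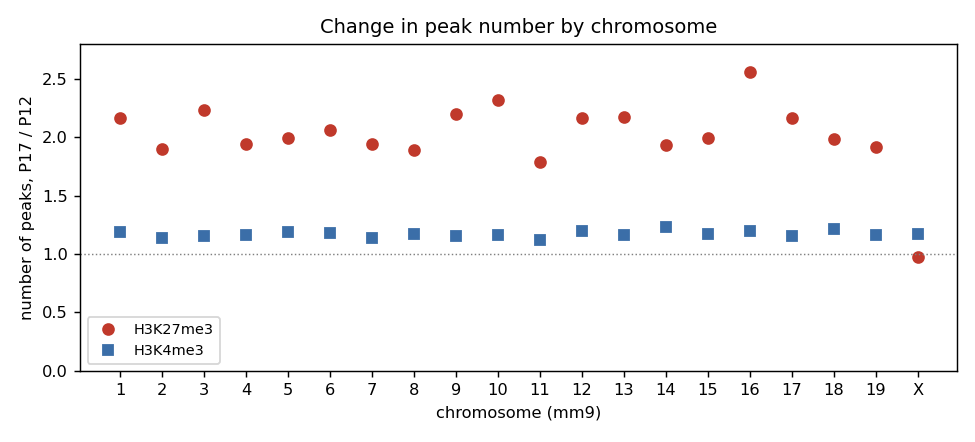
Ratio of the number of called peaks at P17 over P12 (vertical axis) for each mm9 chromosome (horizontal axis), with H3K27me3 as red circles and H3K4me3 as blue squares; the dotted line marks a ratio of 1. For H3K27me3 the autosomes range from 1.79 to 2.56 and the X chromosome stands at 0.975.

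Most regions marked at P12 were also marked at P17. Of P12 H3K27me3 peaks, 95.3% (Wilson 95% interval 94.9% to 95.7%) overlapped a P17 H3K27me3 peak by at least 1 bp, against a mean of 5.44% when the peaks were rotated along each chromosome. Of P12 H3K4me3 peaks, 95.7% (95.5% to 95.8%) overlapped a P17 H3K4me3 peak, against 7.72% after rotation. In the other direction, 80.5% of P17 H3K4me3 peaks but 32.1% (31.5% to 32.6%) of P17 H3K27me3 peaks had a P12 counterpart of the same mark, the latter being 2910 of 26387 peaks when 50% of the peak had to be covered. The 17925 H3K27me3 peaks without a P12 counterpart were narrower (median 2114 bp) than the 8462 with one (4368 bp), and covered 42.0 Mb against 44.4 Mb. The 611 P12 H3K27me3 peaks without a P17 counterpart had a median width of 594 bp, against 1131 bp for the others. For all 4 overlaps the permutation by rotation gave p = 0.001, the smallest 1000 rotations can give (one-sided; adjusted p = 0.00107 by Benjamini-Hochberg over 15 pairs). These p-values test position along the genome in these files, not replication.

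Many H3K27me3 regions also carried H3K4me3 at both stages. At P12, 63.1% (62.3% to 64.0%) of H3K27me3 peaks overlapped H3K4me3, against 5.99% after rotation, and at P17 the share was 63.0% (62.5% to 63.6%) against 10.7%. When 50% of the peak had to be covered, the shares were 55.5% and 47.2%. Regions with both marks at P12 stayed that way: of 8227 such H3K27me3 peaks, 99.3% were covered by H3K27me3 and 99.1% by H3K4me3 at P17. Of the 4801 P12 H3K27me3 peaks without H3K4me3, 88.5% were covered by H3K27me3 and 10.2% by H3K4me3 at P17. Of the 36621 P12 H3K4me3 peaks without H3K27me3, 94.9% were covered by H3K4me3 and 27.1% (26.6% to 27.5%) by H3K27me3 at P17. At P17, H3K4me3 lay on 55.6% of the H3K27me3 peaks without a P12 counterpart and on 78.8% of those with one, against 9.12% and 14.2% after rotation. The permutation by rotation gave p = 0.001 for each of these 4 overlaps, the smallest possible (adjusted p = 0.00107). An overlap of peaks does not separate cells with both marks from mixtures of cells with either mark. Promoters were not assigned, since no annotation of mm9 was used here.

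The P17 sample titled H3K4me3 has an antibody field that names H3K27me3, so its peaks were compared with every other histone-mark list. They overlapped P12 H3K4me3 peaks in 80.5% of cases, P17 H3K27me3 peaks in 35.3% and P12 H3K27me3 peaks in 14.8%. Its median width of 1716 bp lay nearer to the 1483 bp of P12 H3K4me3 than to the 2529 bp of P17 H3K27me3. The sample was treated as H3K4me3, following its title.

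**Figure D3:**
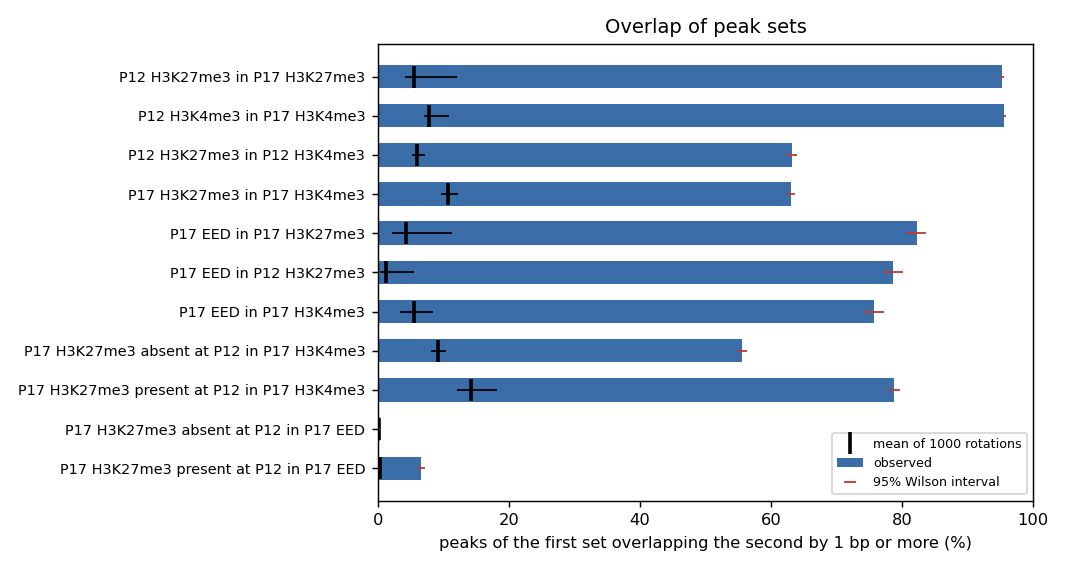
Share of the peaks of 1 set that overlap another by at least 1 bp (horizontal axis, percent) for 11 pairs of sets (vertical axis); blue bars are observed shares with Wilson 95% intervals in red, and black marks the mean and range of 1000 rotations. EED peaks lie in P17 H3K27me3 peaks in 82.3% of cases against a rotated mean of 4.26%.

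Most EED peaks at P17 lay where H3K27me3 was already present at P12. Of 2701 EED peaks, 82.3% (80.8% to 83.7%) overlapped P17 H3K27me3 against 4.26% after rotation, 78.7% (77.1% to 80.2%) overlapped P12 H3K27me3 against 1.17%, and 75.7% (74.0% to 77.3%) overlapped P17 H3K4me3 against 5.50%. Regions with both marks at P17 held 1970 EED peaks (72.9%), H3K27me3 alone held 253, H3K4me3 alone 74, and 404 lay in neither. The 47 EED peaks in the chromosome 6 gap of the P17 H3K27me3 list count here as outside that mark. The 2223 EED peaks in H3K27me3 fell into 600 of the 26387 P17 domains (2.27%), and 50 domains with at least 10 EED peaks held 719 of them. The domain on chromosome 11 at 96129003 to 96219277 held 47 EED peaks, the domain on chromosome 2 at 74482891 to 74555463 held 36, and that on chromosome 15 at 102738509 to 102834200 held 29. The widest EED peak itself lay on chromosome 10 at 50614356 to 50624645 (10290 bp). For the 3 overlaps the permutation by rotation gave p = 0.001, the smallest it can give (adjusted p = 0.00107).

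EED domains were wide ones. The median width of P17 H3K27me3 peaks with EED was 8578 bp, against 2491 bp without (permutation p = 1e-05, the smallest 100000 resamples can give, two-sided). Because wide peaks meet other peaks more often, the width was also measured after rotating the H3K27me3 peaks along each chromosome. The median width of rotated peaks meeting EED averaged 3209 bp and reached at most 5132 bp (permutation by rotation, p = 0.001, the smallest possible). Of 590 P17 domains over 10 kb, 256 (43.4%) held EED. Of H3K27me3 peaks with a P12 counterpart, 6.57% (6.06% to 7.12%) held EED against 0.331% after rotation (permutation by rotation, p = 0.001). Of those without a counterpart, 0.245% (0.183% to 0.329%) did against 0.200% (permutation by rotation, p = 0.138). The odds ratio between the groups was 28.6 (Fisher's exact test, two-sided, p = 9.56e-221). Within 10 width classes it was 3.68 (2.51 to 5.39, Mantel-Haenszel) and within 50 classes 2.69 (1.82 to 3.97). Without the widest of the 10 classes it was 2.39 (1.58 to 3.62). These tests are across peaks of single files, and neighbouring peaks are not independent.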

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

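The settings for totals without multicopy entries, wider peaks, width classes and X chromosome counts, and all settings for genes outside the 20 highest and lowest ratios, were chosen after the data had been seen, and the others before. Over 128 results and 671 alternatives, 637 gave the same call, among them all 112 for the 20 genes with the highest and lowest ratios, 33 of 33 for overlaps and 54 of 56 for gene lists. Many alternatives for genes and lists could hardly change a call. A minimum of reads leaves the ratio and interval of a kept gene as they were, and the pseudocount does not enter the interval. Other totals shift all genes nearly alike, so list medians relative to all genes barely move. For 76 other named genes, 418 of 447 gave the same call against a ratio of 1, 13 lost it, 12 gained it and 4 changed sign with a call in at least 1 of the settings compared. Those 4 were Asic2 at 0.00088 with median-of-ratios factors, Camta1 at 0.055 with TMM and 0.058 with median-of-ratios factors, and Snora19 at -0.0063 with totals without multicopy entries; each is a shift of scale near a ratio of 1. Genes without a call in either setting, such as Ezh1, Bmp6, Fshr, Mll3, Olfr56 and Pax7, also changed sign under other scaling. The number of genes over 2-fold lower moved from 73 to 3 with at least 100 reads, since the lowest ratios belong to genes with few reads, and to 35 with a pseudocount of 5, which pulls in genes of low count by construction. The number of genes over 2-fold higher stayed between 493 and 678. Relative to all genes, the olfactory and vomeronasal receptor median was -0.042 with at least 100 reads and no longer outside the random range, on fewer genes. The spermiogenesis median was -0.10 relative to all genes with TMM and fell just outside the range; the cause was not tested. Merging peaks within 1 kb left 1334 EED peaks of 2701, since many stand close together. TMM moved the all-gene median from -0.08 to -0.002. No paired analysis was possible because each mark and stage had 1 deposited file. The stricter sets by peak score, the promoter windows and the level per kb were not run, since the lists hold no score and neither an mm9 annotation nor gene lengths were used here. Depth limits genes with few reads most: for Hist1h2bl the 95% interval ran from 1.08 to 4.47.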

Other observations

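The tests in this part and its lists of immediate-early and histone genes were chosen after the results had been seen, except the X-linked list and its median, which were planned. Immediate-early response genes, which growth signals switch on within minutes, had a median log2 ratio of 0.88 over 46 genes, against a random range of -0.15 to 0.01. Intervals of 41 lay above the typical gene and of 2 below it, and 21 genes were over 2-fold higher. Zfp36 had the highest ratio and the phosphatase gene Dusp2 the lowest at -0.50. The 2 genes with the highest P17 levels changed less than the median of the list: the nuclear receptor gene Nr4a2 stood at 0.64 (0.55 to 0.74; 1218 and 3767 reads) and the kinase gene Sgk1 at 0.41 (0.32 to 0.49; 1414 and 3709 reads). The median level of the list went from 9.54 CPM (percentile 3.56 among random lists) to 25.8 CPM (percentile 98.2), close to the meiotic prophase genes at 25.4 CPM and under the Hox genes at 54.6 CPM. These levels are per gene without regard to length, so they do not compare the density of the mark between lists. Replication-dependent histone genes, 38 of them measured, had a median of 1.16 (random range -0.23 to 0.07), with 26 above and 0 below the typical gene and 18 over 2-fold higher. Hist1h2be, with the highest P17 level and 423 and 967 reads, stood at only 0.21 (0.04 to 0.38), and Hist1h1e, the next in level, at 1.36 on 68 and 349 reads. The extremes were Hist1h2bn at 2.47 on 2 and 28 reads and Hist1h2bp at -0.89 (-1.81 to -0.03) on 23 and 24 reads. Their median level was 0.891 and 1.78 CPM, so most ratios rest on few reads, and near-identical copies share reads. The members of both lists were written from textbook knowledge after Zfp36, Ier2 and Hist1h2bl had appeared among the highest ratios.

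A gap in the P17 H3K27me3 list stood out. On chromosome 6 (mm9), no P17 H3K27me3 peak lay between 52097777 and 52230508 (133 kb), although the peaks on either side carry consecutive numbers. The interval held 26 P12 H3K27me3 peaks over 114 kb, 47 EED peaks and 23 P17 H3K4me3 peaks. The next gap by this measure, on chromosome 4 at 134715845 to 134734443, held 10.0 kb of P12 H3K27me3. No explanation was tested, and counts that use the P17 list treat this region as unmarked.

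The genes over 2-fold higher at P17 could reflect a P17 pool with higher enrichment over background. Of these 561 genes, 181 (32.3%) had an interval wholly above that of every Hox gene, but they were picked for high ratios and no Hox gene was over 2-fold higher, so this value decides nothing. H3K4me3 material carried into the pool would mark broad H3K4me3 peaks most often. From the narrowest to the widest of 4 width classes of P12 H3K4me3 peaks without H3K27me3, P17 H3K27me3 covered 18.4%, 30.5%, 35.1% and 24.27%, which rises and then falls, and no peak was tied to these genes. Both explanations stay open, as do GC content and gene length, which were not tested, and the stage difference, which coincides with the pooling and depth of the P17 file.

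H3K27me3 peaks on the X chromosome numbered 120 at P12 and 117 at P17, a ratio of 0.975 against 2.04 on the autosomes (range 1.79 to 2.56; odds ratio 0.479, 0.371 to 0.619, Fisher's exact test, two-sided, p = 2.19e-08), while the length they covered was 2.37 times that at P12 on the X and 3.63 to 4.94 times on the autosomes. Deeper pooled reads adding peaks on every chromosome alike would put the X inside the autosomal range, but after merging within 1 kb its ratio was 1.551, still under the autosomal range of 2.13 to 2.99. The odds ratio was then 0.620 (0.458 to 0.840, Fisher's exact test, two-sided, p = 0.00252). Both tests are across peaks of 1 file per stage, and neighbouring peaks are not independent. Low read coverage of the single X in males may hold back calls of a broad mark; the H3K4me3 ratio of 1.176 lay inside the autosomal range by number (1.12 to 1.23), but by covered length 1.33 lay under the lowest autosome at 1.38, so this explanation and a stage difference cannot be told apart. A stage difference in X chromatin would go with the median of -0.319 for X-linked genes in gene-body reads, at percentile 0.21 of random lists. Of these 21 genes, however, 16 had intervals spanning the typical gene. The median also cannot separate a stage difference from higher enrichment over background in the P17 pool. A stage difference remains a hypothesis, since X coverage and enrichment both stay open.

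EED lay mostly on P17 H3K27me3 peaks already present at P12, which may follow from their greater width. The Mantel-Haenszel odds ratio over 10 width classes was 3.681 (2.51 to 5.39), against 28.6 without classes, and over 50 classes 2.69 (1.82 to 3.97). Without the widest of the 10 classes it was 2.39 (1.58 to 3.62), so width as the whole cause is argued against, although the ratio fell with each of these settings. Peaks present at P12 held EED more often in 6 of the classes, less often in 3 and equally often in 1. Neighbouring peaks are not independent, and a higher level of H3K27me3 within peaks was not measured in these lists, so an earlier onset of marking at EED sites stays an untested hypothesis.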
